A study of Mus musculus with 12 samples.

How the data were processed

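RNA from mouse kidney was measured on 12 Affymetrix whole-genome mouse arrays of the 3' type, in 6 groups of 2: tissue, progenitor cells and organoids, each from cortex and from medulla. Per the labels' protocols, progenitor cells were grown on fibroblast feeder cells, organoids were formed in 3D Matrigel, RNA was purified on RNeasy columns, and labelled cRNA was made with a 3' IVT PLUS kit. The labels call the replicates biological and the series' design text speaks of 2 biological samples. They do not say whether equal replicate numbers share an animal or a culture.

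Per the submitters' processing notes, the signals came from MAS5, whose version is not given in the sources used here. The values the authors deposited are log2 signals per probe set. The values themselves showed that each array was scaled to a common target: after trimming 2% at each end, the mean unlogged signal was 500 on every array. MAS5 detection calls were not used here, so no probe set is described as absent and a fold against a dim group depends on the offset below.

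Of 45101 probe sets, 64 controls were left out of the tests. The platform annotation gave 1 gene symbol to 34958 probe sets, several to 932 and none to 9211, controls included. Of the probe sets with 1 symbol, 34754 matched a current mouse gene by gene ID. Probe sets with several symbols or none were not used for gene results. Pax2, on the list of genes to be named, was not analysed here because no probe set named it alone. The probe set with the highest mean over the 12 arrays stood for each of 18193 genes. A gene was tested when that probe set lay above the array median on both arrays of at least 1 group, which left 13037 genes.

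Deposited log2 values were unlogged, 15.1473 signal units (the 25th percentile of all values) were added, and log2 was taken again. This offset shrinks differences of dim genes, so log2 differences understate their change. R 4.3.3 and limma 3.58.1 were used. All 12 arrays entered 1 linear model with 6 group means, 6 residual degrees of freedom and empirical Bayes variances with a mean-variance trend (median prior degrees of freedom 5.67). The spread is thus shared over groups, which matters because the medulla organoid replicates differed more than the others. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of adjusted p = 0.05. Standard errors (SE) come from this model. A stage difference is the mean of its cortex and medulla differences, with 4 arrays on each side. A region difference is medulla minus cortex, with 2 arrays on each side. The number of arrays limits the precision.

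The 25 gene lists, the tests, the main alternatives and the naming rule were fixed before the data were examined. Added after seeing results were the check on other probe sets, the tissue region genes above background in the cultures, and the leaving out of arrays for the region list tests, for the fibroblast count and for the genes shared by progenitors and organoids. So were the overlap test and correlations of region differences between stages and the tests of technical explanations other than the splits of arrays. Lists with at least 5 measured members were tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over the 25 lists within a comparison. Camera with a correlation estimated from these arrays, and limma's fry, were alternatives. The named genes are the 10 largest rises and the 10 largest falls per comparison (5 each way for a difference between region differences) that passed the threshold, changed at least 2-fold and had every array of 1 side above every array of the other. Symbols of unnamed gene models and probe sets marked as cross-hybridizing were passed over. Up to 4 members of each described list past the threshold were added, and 16 measured marker genes were followed whether they changed or not.

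The model was tested on simulated data with 200 of 13037 genes changed. For progenitor against tissue it recovered 67% of genes changed by 1 log2 unit and 91% of those changed by 2, with 8 false calls. For medulla against cortex in tissue the shares were 44% and 79%, with 5 false calls. For the difference between the organoid and progenitor region differences they were 17% and 52%, with 0 false calls. In a simulated medulla tissue shift of 1 list by 0.5, camera called that list and 0 others. The simulated genes varied independently of each other, so this cannot show how often camera calls lists of correlated genes. Each simulated gene also had the same spread in all 6 groups, whereas the real medulla organoid replicates differed more than the others. The simulation therefore cannot show how many false calls comparisons with the medulla organoids hold.

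Alternatives were quantile normalization, 75th percentile scaling, offsets of 1 and of the median signal, 2 other brightness filters, the mean of all probe sets, a fit of the compared groups alone, no variance trend, replicate number as a block, and each array left out in turn. Scaling to the 75th percentile moved the median log2 difference of all genes from -0.29 to -0.51 for organoid against tissue and from -0.289 to -0.404 for organoid against progenitor. Quantile normalization gave -0.384 and -0.359.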

Results

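Expression profiles were compared among whole mouse kidney tissue, cultured renal progenitor cells and organoids grown from such cells, each derived from the outer kidney (cortex) and the inner kidney (medulla). Each of the 6 groups held 2 arrays described as biological replicates. Replicates of a group correlated across genes with r between 0.945 and 0.990. Genes are not independent replicates, so these correlations only describe the arrays. Tissue and progenitor arrays correlated with a median r of 0.611, progenitor and organoid arrays with 0.794, and tissue and organoid arrays with 0.582. The median absolute log2 difference between replicates was 0.414 in medulla organoids and between 0.128 and 0.226 in the other groups.

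The organoid arrays differed from the others in their controls. Poly-A controls, bacterial transcripts that are added to RNA before labelling, had a median log2 signal of 8.26 on tissue arrays, 7.23 on progenitor arrays and 1.43 on organoid arrays. Hybridization controls, added after labelling, had medians of 12.21, 11.67 and 12.55. The 3' minus 5' difference of the Gapdh control probe sets lay between 0.867 and 1.67 on organoid arrays and between -0.405 and -0.298 on progenitor arrays. Since all organoid arrays and no others had low poly-A controls, the organoid stage and this labelling difference cannot be told apart in comparisons of organoids with other stages. Within the organoids the Gapdh difference also moved with region, with 1.53 and 1.67 on the cortex arrays and 1.15 and 0.867 on the medulla arrays. The same difference for beta-actin lay between 0.938 and 1.63 on tissue arrays and between 0.163 and 0.187 on progenitor arrays. Tissue and progenitor arrays did not overlap in the added controls either. Poly-A medians of single arrays lay between 7.96 and 8.83 in tissue and between 7.03 and 7.37 in progenitor cells. Hybridization medians lay between 12.08 and 12.33 in tissue and between 11.66 and 11.72 in progenitor cells. RNA or labelling quality thus also moved with these comparisons, and its effect on them was not tested.

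**Figure D1:**
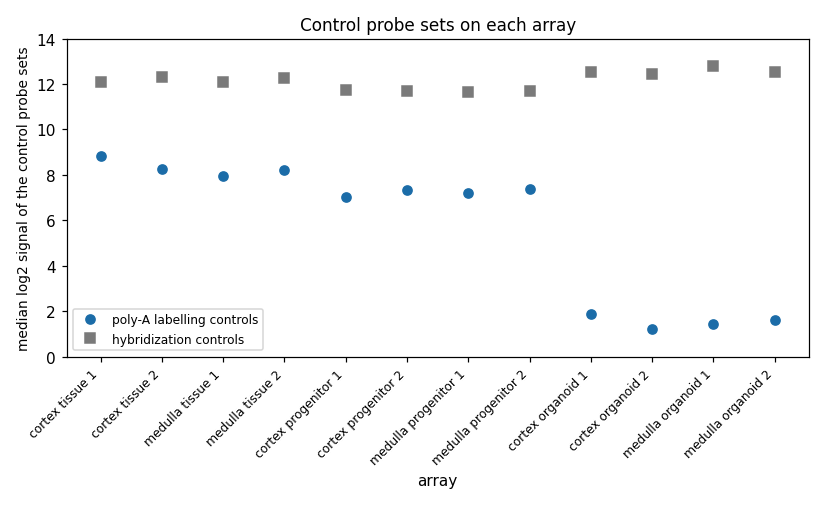
Median log2 signal of the poly-A labelling controls (circles) and the hybridization controls (squares) on each of the 12 arrays, 1 point per array. Poly-A medians are at most 1.88 on the 4 organoid arrays and at least 7.03 on the other 8, while hybridization medians lie between 11.66 and 12.81.

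In progenitor cells compared with tissue, genes of differentiated tubules fell and genes of proliferation, simple epithelium and tubular injury rose. The arrays compared also differed in the beta-actin, poly-A and hybridization controls. With an estimated correlation the simple epithelium, loop of Henle and distal tubule lists lost their camera calls. All 31 measured proximal tubule genes fell, with a median log2 difference of -8.16, among them Miox, which breaks down inositol (-10.45 ± 0.22, SE), Napsa (-10.28 ± 0.33), Kap (-10.27 ± 0.16) and Pck1, an enzyme of gluconeogenesis (-10.26 ± 0.19). The 24 cell cycle genes that rose, of 26, included Bub1 (6.16 ± 0.23), Cdk1 (5.70 ± 0.26), Top2a (5.45 ± 0.17) and Mki67 (5.37 ± 0.17), and the list median was 4.44. Of 18 tubular progenitor and injury genes, 14 rose and 2 fell, with Lcn2 (7.39 ± 0.27), the kidney injury molecule Havcr1 (7.26 ± 0.17), Cxcl2 (6.90 ± 0.13) and Krt20 (6.86 ± 0.17) the largest.

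Other segments of the nephron fell as well. Umod, a urinary protein (-10.03 ± 0.13), the salt transporter Slc12a1 (-8.95 ± 0.21), Egf (-8.91 ± 0.19) and the potassium channel Kcnj1 (-8.23 ± 0.25) led the 13 of 15 loop of Henle genes that fell. In the distal convoluted and connecting tubule list 11 of 12 genes fell, including Calb1 (-9.31 ± 0.17), S100g (-8.77 ± 0.20), Kl (-8.06 ± 0.33) and Slc12a3 (-8.03 ± 0.32). Of the 18 genes listed for principal cells of the collecting duct 15 fell and 2 rose, with Rhcg (-7.08 ± 0.37) and the water channels Aqp3 (-5.86 ± 0.29), Aqp4 (-5.76 ± 0.19) and Aqp2 (-5.29 ± 0.25) among the falls. All 15 intercalated cell genes fell, led by Car15 (-6.69 ± 0.37) and the anion exchangers Slc4a1 (-5.87 ± 0.26) and Slc26a4 (-5.76 ± 0.20). All 17 fatty acid oxidation genes fell too, among them Ehhadh (-7.18 ± 0.14), the coactivator Ppargc1a (-5.83 ± 0.16) and Ppara (-5.32 ± 0.26).

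Markers of other kidney cells moved in the same comparison. Endothelial genes fell in 17 of 18 cases, with Plvap (-6.88 ± 0.27), Emcn (-5.87 ± 0.26) and Pecam1 (-3.75 ± 0.26), and immune cell genes fell in 12 of 13, with Cd74 (-5.19 ± 0.23) and Ptprc (-2.69 ± 0.19). Podocyte genes fell in 10 of 13 cases, including Tcf21 (-6.24 ± 0.27) and Ptpro (-4.31 ± 0.41). Of 19 fibroblast and mesenchyme genes 13 rose and 3 fell, with Col1a1 at 3.28 ± 0.12, Prrx1 at 2.80 ± 0.33 and Lum at -2.45 ± 0.25, and the list did not pass against the other genes (adjusted p = 0.0511, limma camera). The progenitor cells had been grown on fibroblast feeder cells.

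Simple epithelial genes rose in 17 of 18 cases, including the keratins Krt19 (6.67 ± 0.24) and Krt18 (4.98 ± 0.11) and the tight junction claudin Cldn4 (4.29 ± 0.16). Epcam (1.06 ± 0.17), Cdh1 (0.77 ± 0.12), Pax8, a transcription factor of the renal lineage (0.88 ± 0.11), Sox9 (4.48 ± 0.29) and Vim (0.69 ± 0.13) also rose. Six2, a marker of embryonic nephron progenitors, did not pass (0.41 ± 0.25, adjusted p = 0.151), nor did the basal keratin Krt5 (-0.66 ± 0.29, adjusted p = 0.0597), while Trp63 fell (-1.58 ± 0.35). Immediate early genes rose in 17 of 17 cases, led by Fos (5.93 ± 0.18), and YAP target genes in 11 of 15, led by Ankrd1 (6.13 ± 0.25) and Ccn1 (4.97 ± 0.15). Of the cholesterol synthesis genes 11 of 15 rose, led by Fdps (4.88 ± 0.12), and of the basal and stratified epithelium genes 9 of 14 rose and 3 fell, led by Lamb3 (5.02 ± 0.22).

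The largest rises of single genes were those of the chemokines Cxcl5 (8.74 ± 0.10) and Ppbp (7.83 ± 0.16), of Hmga2, a chromatin protein of embryonic cells (7.80 ± 0.19), and of Prss22 (7.63 ± 0.29), Plekhs1 (7.46 ± 0.15), Cdkn2a (7.20 ± 0.28) and Msln (7.13 ± 0.19). Besides the proximal tubule genes above, the largest falls included Klk1 (-10.83 ± 0.30), Hao2 (-10.55 ± 0.45), Cltrn (-10.30 ± 0.19), Acsm2 (-10.22 ± 0.20) and Cyp2j5 (-10.09 ± 0.25). The endocytic receptor Lrp2 (-8.58 ± 0.29) and the phosphate transporter Slc34a1 (-8.53 ± 0.24) fell as well. In all, 4801 genes rose and 4676 fell at adjusted p under 0.05 in limma (9477 of 13037), and 5736 of these changed at least 2-fold. Camera called 18 of the 25 lists, 7 up and 11 down. With an estimated correlation 6 of them passed: cell cycle (adjusted p = 0.00828), fatty acid oxidation and tubular progenitor and injury (both 0.0206), intercalated cell (0.0256), and proximal tubule and collecting duct principal cell (both 0.0262). Adjusted p with an estimated correlation was 0.0504 for immediate early, 0.0583 for cholesterol synthesis, 0.0585 for endothelium, 0.0854 for simple epithelium and for the distal list, 0.126 for loop of Henle, immune cell, podocyte and basal epithelium, and 0.224 for YAP targets. Adjusted over the list alone, the counts of the lists above were the same except that 4 basal genes fell. Other bright probe sets of the called genes had the same sign in 81.6% of cases and were called the opposite way in 6.89%, and 2586 genes had every such probe set called the same way, a check chosen after seeing the data.

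**Figure D2:**
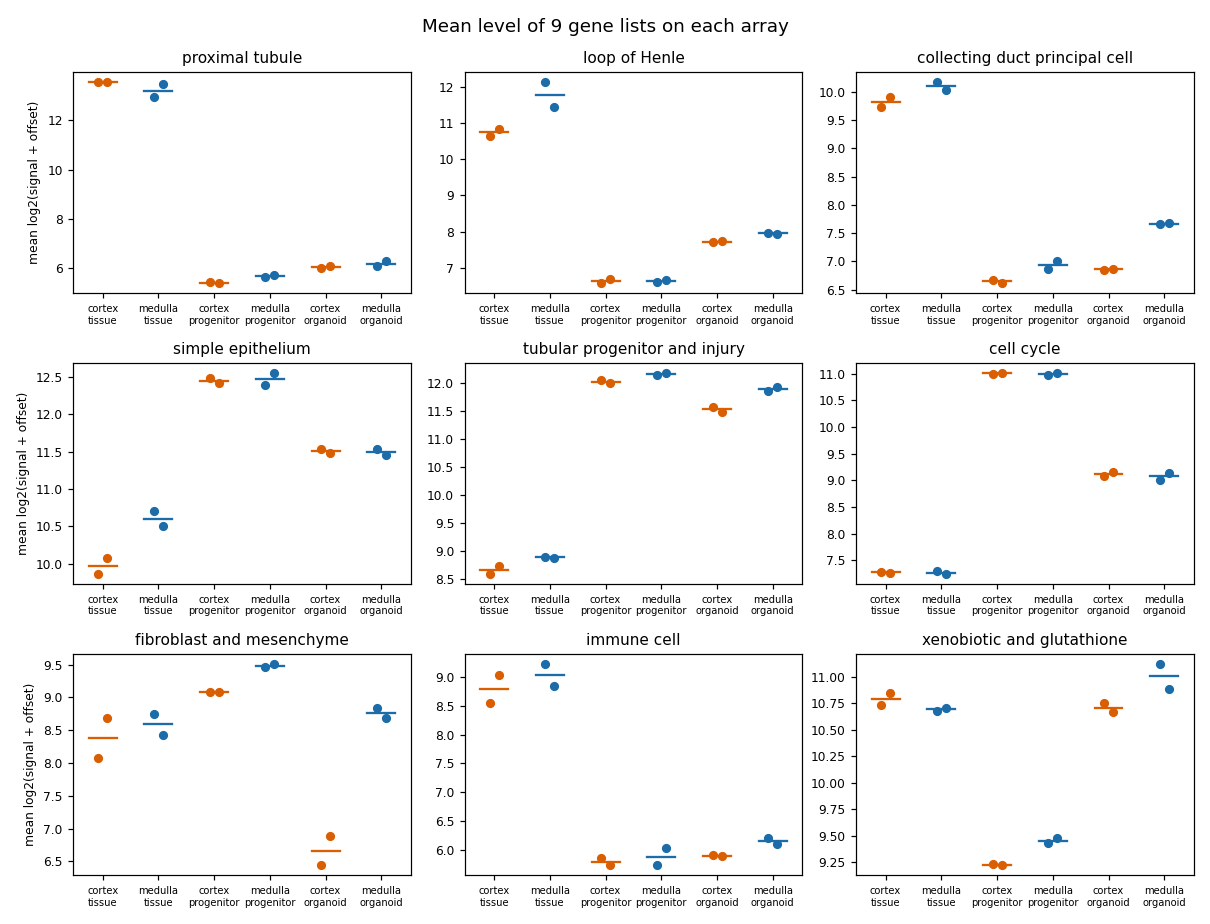
Mean log2(signal + offset) of the measured members of 9 gene lists on each of the 12 arrays (points) with the mean of each group of 2 (lines), cortex in orange and medulla in blue; each panel has its own axis, which does not start at 0. The proximal tubule mean is 12.97 or higher on tissue arrays and 6.27 or lower on all others, and the fibroblast mean is lowest on the 2 cortex organoid arrays (6.44 and 6.89).

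In organoids compared with progenitor cells, cell cycle and fibroblast genes were lower and genes of xenobiotic and glutathione metabolism were higher, on arrays whose poly-A controls also differed. All 3 calls were lost with an estimated correlation (adjusted p = 0.052, 0.664 and 0.428). Single genes of several tubule segments rose while others of the same segments fell. Some falls lay between low levels: group means of Slc34a1 were 5.70 and 5.90 in progenitor cells and 4.97 and 4.46 in organoids. Such falls depend on the offset and do not show the loss of a segment. Umod rose by 6.05 ± 0.13 on the log2 scale, and 8 of 15 loop of Henle genes rose in all, including the claudins Cldn10 (4.54 ± 0.19) and Cldn16 (3.52 ± 0.29) and Kcnj1 (3.42 ± 0.25), while 5 fell. Among intercalated cell genes 6 rose and 4 fell of 15, with Slc26a4 at 5.76 ± 0.20 and the proton pump subunit Atp6v0d2 at 5.48 ± 0.23. Among proximal tubule genes 10 rose and 9 fell of 31, with Kap (5.99 ± 0.16) and the amino acid transporter subunit Slc3a1 (4.26 ± 0.13) up. None of these 3 lists passed in camera (adjusted p = 0.0855, 0.292 and 0.248).

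Of 26 cell cycle genes 24 fell, with a list median of -1.83, including Bub1 (-4.01 ± 0.23), Plk1 (-3.98 ± 0.23), Top2a (-3.53 ± 0.17) and Mki67 (-0.98 ± 0.17). Among 19 fibroblast and mesenchyme genes Col1a1 rose (1.37 ± 0.12), but its other bright probe set was not called. In that list 16 genes fell, with Col3a1 (-4.12 ± 0.23), Col5a2 (-4.05 ± 0.21) and Col6a3 (-3.21 ± 0.33). This average joined unlike regions: the mean log2 signal of the list was 9.08 on both cortex progenitor arrays and 6.44 and 6.89 on the cortex organoid arrays, and 9.46 and 9.51 against 8.84 and 8.69 for the medulla. Genes of xenobiotic and glutathione metabolism rose in 12 of 16 cases, led by Cyp1a1 (4.16 ± 0.27), the cystine transporter subunit Slc7a11 (3.34 ± 0.22), Gsta4 (2.74 ± 0.14) and Gsta2 (2.69 ± 0.25). Of 18 simple epithelial genes 12 fell and 2 rose, with Cldn4 at -3.17 ± 0.16 and Krt8 at -1.75 ± 0.11, and the list did not pass (adjusted p = 0.0855).

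The largest rises were in Chil4 (7.90 ± 0.33), the calcium-binding proteins S100g (7.63 ± 0.20), S100a8 (7.62 ± 0.16) and S100a9 (7.52 ± 0.29), the immunoglobulin receptor Pigr (7.59 ± 0.14), Pde1c (7.27 ± 0.27), Vnn3 (7.03 ± 0.20), Akr1c18 (6.82 ± 0.15), the transporter Slc7a12 (6.82 ± 0.19) and Chil1 (6.68 ± 0.34). The largest falls were in Pik3cd (-9.36 ± 0.14), Pdgfb (-6.73 ± 0.21), the N-cadherin gene Cdh2 (-6.15 ± 0.13), Eya4 (-5.73 ± 0.27), Mab21l4 (-5.14 ± 0.22), the muscle actins Acta1 (-5.06 ± 0.20) and Acta2 (-4.75 ± 0.34), Stmn2 (-4.94 ± 0.27), Sema3e (-4.81 ± 0.17) and Wnt7a (-4.66 ± 0.24). Pik3cd rests on 1 of its 6 probe sets, the only one above the brightness filter. Epcam (-0.69 ± 0.17), Cdh1 (-1.37 ± 0.12), Six2 (-2.09 ± 0.25), Slc34a1 (-1.09 ± 0.24), Krt5 (-0.78 ± 0.29) and Pecam1 (-0.69 ± 0.26) fell, and Pax8 (0.72 ± 0.11), Sox9 (1.05 ± 0.29) and Ptprc (3.18 ± 0.19) rose. Group means of log2 signal of Six2, Slc34a1, Krt5 and Pecam1 were at most 6.47, 5.90, 5.78 and 5.54 in both stages. The size of their falls depends on the offset. The other bright probe set of Epcam and that of Sox9 were not called. The immune cell list did not move like Ptprc. Its mean log2 signal lay between 5.73 and 6.02 on progenitor arrays and between 5.88 and 6.20 on organoid arrays. Lrp2 (0.27 ± 0.29, adjusted p = 0.418), Aqp2 (-0.23 ± 0.25, adjusted p = 0.411), Vim (-0.09 ± 0.13, adjusted p = 0.517) and Trp63 (0.34 ± 0.35, adjusted p = 0.396) did not pass. For Vim this average joined unlike regions: group means of log2 signal were 11.31 in progenitor cells and 10.05 in organoids of the cortex, and 11.83 and 12.90 in those of the medulla.

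In limma 3657 genes rose and 5771 fell (9428), 5593 of them at least 2-fold, and the median log2 difference of all genes was -0.289. Camera called 3 lists, cell cycle (adjusted p = 9.59e-05) and fibroblast (0.0437) down and xenobiotic and glutathione (0.00144) up. Adjusted over the list alone, the counts of these 3 lists were unchanged. Other bright probe sets of the called genes had the same sign in 60.1% of cases and were called the opposite way in 26.9%, and 1655 genes had every such probe set called the same way, a check chosen after seeing the data.

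The 3 stages allow the genes that fell from tissue to progenitor cells to be followed into organoids. Of the 4676 genes that fell, 1753 (37.5%) rose again in organoids, and 791 of these (45.1%) still lay below tissue while 470 (26.8%) lay above it. Of the 20 largest returns, 13 lay above tissue, such as Vnn3 (6.27), S100a9 (6.16) and Pigr (2.75, log2 difference between organoids and tissue). Some of them had been low in tissue. Group means of log2 signal of Vnn3 were 6.23 and 5.30 in tissue and 5.26 and 4.75 in progenitor cells. Those of S100a9 were 5.28 and 5.89, and 4.345 and 4.11. Such small falls between low levels depend on the offset, so these rises do not show the return of a tissue level. Others stayed below it, such as S100g, Slc7a12, Umod and Kap, whose log2 differences between organoids and tissue were -1.13, -2.61, -3.98 and -4.29. The lactate transporter Slc5a8 rose by 6.56 ± 0.10 and did not differ detectably from tissue (-0.06, adjusted p = 0.613). By list, 8 of 13 fallen loop of Henle genes rose, 6 of 15 intercalated cell genes, 6 of 15 principal cell genes, 5 of 11 distal genes, 10 of 31 proximal tubule genes and 11 of 11 xenobiotic and glutathione genes, against 0 of 17 endothelial genes. Of the 4801 genes that had risen, 2875 (59.9%) fell in organoids.

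Independent lists of these sizes would share 1312 and 2125 genes. Independence is not a neutral reference, because genes at background in progenitor cells can only rise or stay. Both comparisons also use the same variance of each gene. Splitting the progenitor arrays, as below, removes neither, so an excess over these values does not by itself show a return. With the progenitor arrays split between the comparisons the counts were 1348 and 1347 for the returns, where independent lists of the sizes called in the split fits would share 955 and 966. They were 2220 and 2214 for the reverse, against 1543 and 1535. The split also leaves fewer progenitor arrays in each comparison, so how far sharing them adds to the unsplit counts was not tested. The labelling difference of the organoid arrays enters every one of these counts.

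Organoids compared with tissue had lower levels of the genes of most differentiated kidney cells, again on arrays whose poly-A controls differed. None of the lists that camera called down kept its call with an estimated correlation. All 31 proximal tubule genes fell, including Fbp1 (-10.54 ± 0.19), Miox (-10.27 ± 0.22), Slc34a1 (-9.61 ± 0.24), Slc22a7 (-9.33 ± 0.19) and Lrp2 (-8.31 ± 0.29). Loop of Henle genes fell in 11 of 15 cases, with Slc12a1 at -9.91 ± 0.21, Egf at -9.53 ± 0.19 and Umod at -3.98 ± 0.13. Principal cell genes in 16 of 18, with Rhcg at -6.51 ± 0.37 and Aqp2 at -5.52 ± 0.25. Endothelial genes fell in 17 of 18 cases, with Plvap at -7.09 ± 0.27 and Pecam1 at -4.45 ± 0.26, smooth muscle and pericyte genes in 9 of 9, with Rgs5 at -5.86 ± 0.38, and immune cell genes in 11 of 13, with Cd74 at -4.80 ± 0.23.

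Cell cycle genes lay above tissue in 23 of 26 cases, with Mki67 at 4.39 ± 0.17 and Rrm2 at 4.07 ± 0.11. Tubular progenitor and injury genes did so in 15 of 18, with Havcr1 at 7.42 ± 0.17, Cxcl2 at 7.39 ± 0.13 and Lcn2 at 6.60 ± 0.27. Sox9 (5.54 ± 0.29), Pax8 (1.60 ± 0.11), Col1a1 (4.65 ± 0.12) and Ptprc (0.49 ± 0.19) rose. The fibroblast list did not rise with Col1a1. Its mean log2 signal was 8.08 and 8.69 on cortex tissue arrays and 6.44 and 6.89 on cortex organoid arrays. For the medulla it was 8.75 and 8.43 in tissue and 8.84 and 8.69 in organoids. Vim passed on average over the regions (0.59 ± 0.13), with group means of 10.77 in tissue and 10.05 in organoids of the cortex and 10.99 and 12.90 in those of the medulla, and 1 of its 2 other probe sets was called the opposite way. Cdh1 (-0.60 ± 0.12), Six2 (-1.68 ± 0.25), Krt5 (-1.43 ± 0.29) and Trp63 (-1.24 ± 0.35) fell, while Epcam did not pass (0.38 ± 0.17, adjusted p = 0.0645). Six2 lay low in both stages, with group means of log2 signal of at most 6.02, so the size of its fall depends on the offset. The largest rises were in Cxcl5 (9.77 ± 0.10), Prl6a1 (8.79 ± 0.17), the acute-phase protein Hp (8.04 ± 0.25), Hmga2 (8.02 ± 0.19), Clca3b (7.97 ± 0.20), the antimicrobial protein Ltf (7.67 ± 0.20), the chemokine Ccl20 (7.55 ± 0.14) and Chil4 (7.44 ± 0.33). Further large falls were in Ugt3a2 (-9.95 ± 0.17), Pik3cd (-9.91 ± 0.14), Rdh16f2 (-9.76 ± 0.26), Hpd (-9.75 ± 0.21), Cyp4a31 (-9.60 ± 0.23) and Hao2 (-9.60 ± 0.45).

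In limma 4308 genes rose and 6081 fell (10389), 6956 of them at least 2-fold. Camera called 16 lists, 6 up and 10 down. With an estimated correlation the adjusted p was 0.0262 for cell cycle and 0.0344 for tubular progenitor and injury, which passed, and 0.0781 for proximal tubule and principal cell, 0.115 for endothelium, 0.135 for smooth muscle, 0.296 for immune cell and 0.378 for loop of Henle, which did not. Adjusted over the list alone, the counts of these lists were unchanged. Other bright probe sets of the called genes had the same sign in 66.8% of cases and were called the opposite way in 23.9%, and 2342 genes had every such probe set called the same way, a check chosen after seeing the data.

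Medulla tissue differed from cortex tissue mainly by genes that were higher in medulla. The urea transporter Slc14a2 of the inner medulla (5.82 ± 0.50), Corin, which processes atrial natriuretic peptide (5.23 ± 0.54), and Sptssb, a subunit of the sphingolipid-forming serine palmitoyltransferase (4.90 ± 0.41), rose the most. They were followed by Psca (3.71 ± 0.41), Sprr1a (3.58 ± 0.38), the transcription factors Foxa1 (3.35 ± 0.39) and Uncx (3.15 ± 0.44), the keratin Krt15 (3.31 ± 0.40), Fxyd3 (3.26 ± 0.21) and the uroplakin Upk3b (3.14 ± 0.35). Ikbke was the only gene that fell (-1.43 ± 0.23). A second probe set of Slc14a2 differed by 0.317. The other bright probe sets of Sptssb and of Upk3b were not called, and the remaining genes named here had no other bright probe set. The SD of the 2 medulla tissue replicates was 1.31 for Slc14a2, 1.32 for Corin, 1.14 for Sprr1a and 1.03 for Uncx. For the other rises named here it lay between 0.295 (Sptssb) and 0.788 (Foxa1). The SE come from the spread shared over all groups, so they can understate the uncertainty of the genes with the larger SD.

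Simple epithelial genes shifted up (median 0.476, camera adjusted p = 3.04e-10, but adjusted p = 0.102 with an estimated correlation), with Krt19 (2.58 ± 0.34) and Krt18 (1.25 ± 0.16) called. Basal and stratified epithelium genes shifted up as well (median 0.786, adjusted p = 0.000144, but adjusted p = 0.102 with an estimated correlation), with Krt15 and Dst (0.74 ± 0.13) called of 14 and 5 adjusted over the list alone. The lists that follow lost their calls with an estimated correlation (adjusted p = 0.172 for each). Loop of Henle genes shifted up (median 0.707, adjusted p = 1.86e-08) with 1 of 15 called, Slc14a2, whose second probe set differed by 0.317. Osmolyte and hypertonicity genes also shifted up (median 0.79, adjusted p = 0.000179) with 2 of 9 called, again Slc14a2 and the inositol transporter Slc5a3 (1.08 ± 0.16). Proximal tubule genes shifted down by a median of only -0.308 (adjusted p = 3.81e-05) and podocyte genes by -0.413 (adjusted p = 0.0101), with no single member called in limma at adjusted p under 0.05. Adjusted over the list alone, 9 of 18 simple epithelial genes, 8 of 15 loop of Henle genes and 4 of 9 osmolyte genes rose, and 0 of 31 proximal tubule and 0 of 13 podocyte genes fell. Without medulla tissue replicate 1 the proximal tubule median was -0.066 (adjusted p = 0.154) and the podocyte median -0.096 (adjusted p = 0.442), and without cortex tissue replicate 2 the podocyte adjusted p was 0.11.

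In limma 43 genes rose and 1 fell, 40 of them at least 2-fold, and camera called 14 lists, 11 up and 3 down, with 0 called at an estimated correlation. None of the 16 marker genes passed (limma): the values were 2.19 ± 0.41 for Krt5 (adjusted p = 0.0547), 1.15 for Trp63, 1.11 for Epcam, 0.81 for Aqp2, 0.55 for Mki67, 0.48 for Cdh1 and Pax8, 0.22 for Vim, 0.16 for Ptprc, 0.14 for Col1a1, 0.12 for Pecam1, 0.09 for Umod, -0.29 for Six2, -0.31 for Lrp2, -0.41 for Slc34a1 and -0.44 for Sox9. The count of 44 was 14 and 24 without cortex tissue replicates 1 and 2, and 25 and 229 without medulla tissue replicates 1 and 2. It was 23 without either cortex progenitor array, 26 without either medulla progenitor array, 24 without either cortex organoid array, and 122 and 127 without medulla organoid replicates 1 and 2. It was 1 when only the 4 tissue arrays were fitted, 1 for genes whose other bright probe sets were all called the same way (chosen after seeing the data), 21 without the variance trend and 27 with the mean of all probe sets.

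In progenitor cells, most genes that differed between regions were higher in medulla-derived cultures. Slc27a2, a fatty acid transporter of the proximal tubule (3.12 ± 0.23), Adgrf5 (2.96 ± 0.43), Sprr2f (2.88 ± 0.22), Gzmd (2.73 ± 0.32), P2rx2 (2.45 ± 0.36), the receptor Kit (2.37 ± 0.34), the aminopeptidase Enpep (2.36 ± 0.32), Stk26 (2.23 ± 0.34), Cdo1 (2.17 ± 0.22) and Gpx3 (2.16 ± 0.19) rose the most. The water channel Aqp1 (2.06 ± 0.30) and Gata3, a transcription factor of the collecting duct (1.81 ± 0.28), were also higher. Clec2d (-1.82 ± 0.15), Fuom (-1.28 ± 0.16), Irs1 (-1.12 ± 0.20) and Klf4 (-1.01 ± 0.15) were lower. The other bright probe sets of Adgrf5 and of Stk26 were not called, while those of Gzmd and of Klf4 were called the same way. The fibroblast list shifted up by a median of 0.506 (camera adjusted p = 0.000202, and adjusted p = 0.388 with an estimated correlation), with 0 of 19 members called over all genes and 3 adjusted over the list alone. The smooth muscle and pericyte list shifted up by a median of 0.64 (camera adjusted p = 0.0117, and adjusted p = 0.388 with an estimated correlation), with 0 of 9 members called and 1 adjusted over the list alone.

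In limma 36 genes rose and 5 fell, 36 of the 41 at least 2-fold. Camera called 9 lists, 6 up and 3 down, none with an estimated correlation, where the lowest adjusted p was 0.388. None of the 16 marker genes passed in limma: they ranged from -0.66 ± 0.19 for Umod (adjusted p = 0.324) to 0.90 ± 0.37 for Pecam1 (adjusted p = 0.86), with Col1a1 at 0.63, Trp63 at -0.58, Vim at 0.52, Six2 at 0.37, Pax8 at 0.23, Slc34a1 at 0.20, Aqp2 at 0.19, Cdh1 at -0.16, Krt5 at 0.12, Sox9 at -0.09, Epcam and Lrp2 at 0.08, Mki67 at -0.07 and Ptprc at -0.05. The count of 41 was 19 and 20 without cortex progenitor replicates 1 and 2, 13 and 15 without medulla progenitor replicates 1 and 2, and 105 without either medulla organoid array. It was 145 when only the 4 progenitor arrays were fitted, 63 with the larger offset and 4 in the same check on other probe sets.

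Region differences of progenitor cells and tissue were then compared. Gzmd (3.67 ± 0.45), Slc27a2 (3.12 ± 0.32), Sprr2f (2.88 ± 0.31), Enpep (2.84 ± 0.45) and Spink8 (2.58 ± 0.26) had a larger medulla minus cortex difference in progenitor cells. Corin (-5.20 ± 0.76), Slc14a2 (-5.16 ± 0.70), Sptssb (-4.82 ± 0.57), Sprr1a (-4.29 ± 0.53) and Foxa1 (-3.83 ± 0.55) had a larger one in tissue. Loop of Henle genes (median -0.777, camera adjusted p = 9.32e-07) and simple epithelial genes (median -0.484, adjusted p = 9.32e-07) shifted down in this contrast. Of these, 1 of 15 and 0 of 18 members passed, and 7 (with 1 rise) and 2 fell adjusted over the list alone. With an estimated correlation the adjusted p was 0.187 for both. Camera called 11 lists in this contrast, 3 up and 8 down, and 0 of them with an estimated correlation. In limma 21 genes rose and 16 fell. The count of 37 was 18 and 21 without cortex tissue replicates 1 and 2, 20 and 122 without medulla tissue replicates 1 and 2, 14 and 18 without cortex progenitor replicates 1 and 2, 11 and 15 without medulla progenitor replicates 1 and 2, and 91 and 92 without medulla organoid replicates 1 and 2. It was 71 in a fit of the 4 groups compared, 23 without the variance trend and 4 in the check on other probe sets.

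In organoids, mesenchymal genes were higher in those from medulla, on arrays whose Gapdh control also differed between regions. The fibroblast list passed in camera (adjusted p = 9.18e-14) but not with an estimated correlation (adjusted p = 0.121). Of 19 fibroblast and mesenchyme genes 16 were higher in medulla organoids, with a median log2 difference of 2.18, including the collagens Col6a1 (3.36 ± 0.30) and Col6a3 (3.33 ± 0.46), the proteoglycan Dcn (3.13 ± 0.32), Vim (2.85 ± 0.18) and Col1a1 (1.37 ± 0.17). Smooth muscle and pericyte genes did not follow, with a median of -0.261 (adjusted p = 0.716) and 0 of 9 members called in limma. Of 18 principal cell genes 8 were higher in medulla organoids, led by Gata3 (3.54 ± 0.28), Fxyd4 (2.48 ± 0.40), Stc1 (2.09 ± 0.27) and Aqp4 (2.07 ± 0.27). Interferon response genes were lower in 5 of 13 cases, including Oasl2 (-1.48 ± 0.32) and Usp18 (-1.47 ± 0.35). With an estimated correlation neither the principal cell list (adjusted p = 0.121) nor the interferon list (adjusted p = 0.704) passed.

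**Figure D3:**
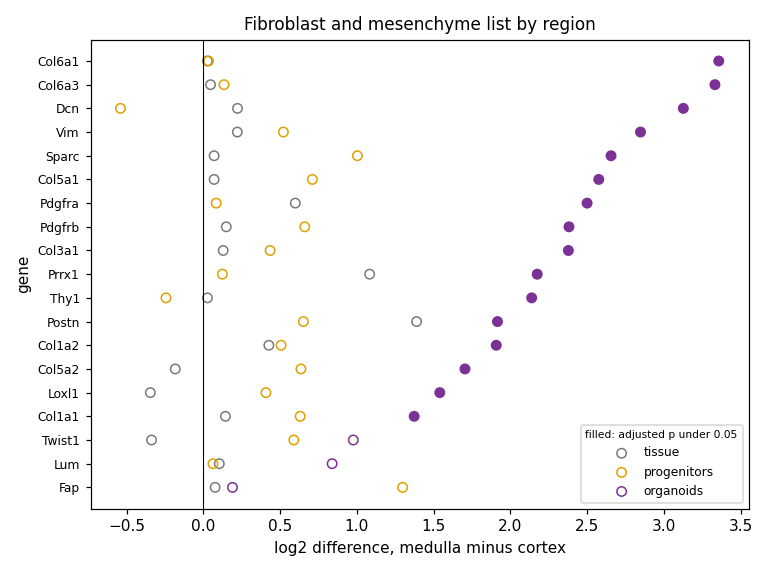
Medulla minus cortex log2 difference of the 19 measured fibroblast and mesenchyme genes in tissue (grey), progenitors (yellow) and organoids (purple), from the limma fit of 2 arrays per group, filled where adjusted p is under 0.05. Of the organoid points 16 are filled, from 1.37 for Col1a1 to 3.36 for Col6a1, and no tissue or progenitor point is.

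The largest rises in medulla organoids were in the acute-phase protein Saa1 (5.01 ± 0.47), the matrix protein Mgp (4.37 ± 0.25), the chemokine Ccl7 (4.25 ± 0.41), S1pr3 (3.99 ± 0.53), Tmem52b (3.93 ± 0.40), Tshz3 (3.68 ± 0.38), Aqp1 (3.57 ± 0.30), S100a7l2 (3.57 ± 0.44) and Afp (3.46 ± 0.35). The largest falls were in Padi1 (-4.14 ± 0.39), Cxcl15 (-3.84 ± 0.46), Tmprss11a (-3.67 ± 0.41), Enpp3 (-3.44 ± 0.35), Klk1b21 (-3.36 ± 0.65), Wfdc18 (-3.36 ± 0.56), Rapgefl1 (-3.24 ± 0.37), Cxcl14 (-3.23 ± 0.39), Arg1 (-3.11 ± 0.30) and Klk1b27 (-3.09 ± 0.39). The SD of the 2 medulla organoid replicates was 1.51 for Klk1b21, 1.2 for S1pr3 and Wfdc18, and 1 for Cxcl14. For the other rises and falls named here it lay between 0.0171 (Tmem52b) and 0.762 (Aqp1). The shared SE can understate the uncertainty of the genes with the larger SD. The other bright probe set of S1pr3 was not called, and 2 of 3 of Enpp3 were called the same way. Umod was lower (-0.67 ± 0.19, adjusted p = 0.0287) and Krt5 higher (1.53 ± 0.41, adjusted p = 0.0247). Pax8 (0.46 ± 0.15, adjusted p = 0.0519), Trp63 (0.73), Slc34a1 (-0.51), Aqp2 (-0.51), Epcam (-0.43), Sox9 (0.38), Six2 (0.33), Pecam1 (0.28), Lrp2 (-0.16), Cdh1 (-0.08), Ptprc (0.06) and Mki67 (0.02) did not pass.

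In limma 1035 genes rose and 1306 fell (2341), 1104 of them at least 2-fold. Camera called 3 lists, fibroblast (adjusted p = 9.18e-14) and principal cell (0.00343) up and interferon response (0.0362) down. Adjusted over the list alone, 18 fibroblast genes rose, 8 principal cell genes rose and 1 fell, and 6 interferon genes fell. Without medulla organoid replicate 2 the principal cell adjusted p was 0.058, and the interferon adjusted p was 0.116, 0.113 and 0.0825 without cortex organoid replicate 1 and medulla organoid replicates 1 and 2. The count of 2341 was 240 when only the 4 organoid arrays set the spread, 186 for genes whose other bright probe sets were all called the same way (chosen after seeing the data), 1227 and 1060 without cortex organoid replicates 1 and 2, and 4316 without medulla organoid replicate 2.

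The region difference of organoids exceeded that of progenitor cells most for Saa1 (5.31 ± 0.67), S1pr3 (4.06 ± 0.74), Ccl7 (3.78 ± 0.58), Dcn (3.67 ± 0.45) and Tmem52b (3.66 ± 0.57), and lay below it most for Tmprss11a (-3.98 ± 0.57), Cxcl15 (-3.95 ± 0.65), Akr1c14 (-3.87 ± 0.44), the Wnt inhibitor Dkk2 (-3.76 ± 0.89) and Enpp3 (-3.70 ± 0.49). Of the fibroblast genes 8 of 19 passed upward, with a median of 1.72 (camera adjusted p = 2.84e-10, and adjusted p = 0.328 with an estimated correlation), and 14 did adjusted over the list alone. In limma 212 genes rose and 323 fell. The count of 535 was 329 and 320 without cortex tissue replicates 1 and 2, 124 and 128 without cortex progenitor replicates 1 and 2, 158 and 145 without medulla progenitor replicates 1 and 2, 212 and 179 without cortex organoid replicates 1 and 2, 1610 and 2509 without medulla organoid replicates 1 and 2, 266 in a fit of the 4 groups compared, and 31 in the check on other probe sets.

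The 43 genes higher in medulla tissue were followed in the cultures, to ask whether cells from each region carry its tissue differences. In progenitor cells 19 of the 43 had the same sign, the median log2 difference was -0.042, and Plet1 was the only member called (limma). In organoids 18 of 43 had the same sign with a median of -0.030, Dst and Upk3b were called higher in medulla, and Pof1b and Tcim were called lower. A common movement of the 43 genes was not detected by limma's fry, a rotation test, in progenitor cells or in organoids. Some of the 43 lay near background in the cultures; among the 35 above the array median in progenitor cells 15 had the same sign (median -0.077), and among the 34 in organoids 14 did (median -0.095), a check chosen after seeing the data. Fry's test of all 43 for changes in mixed directions passed in organoids and not in progenitor cells, but 18% of all genes were called between organoid regions, against 4 of these 43. Plet1, Pof1b and Tcim fall outside the naming rule and were named after their values were seen. The only gene higher in cortex tissue, Ikbke, was too few for a test.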

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

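The splits of the arrays and the comparisons of region differences between stages were planned before results were seen, and the tests of explanations below were chosen after the patterns were seen.

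Several results were singled out because a region difference was itself different between stages by a test of that difference. Between progenitor cells and tissue 37 genes passed, with log2 differences of 3.67 for Gzmd, 3.12 for Slc27a2, 2.88 for Sprr2f, 2.84 for Enpep, 2.58 for Spink8, -5.20 for Corin, -5.16 for Slc14a2, -4.82 for Sptssb, -4.29 for Sprr1a and -3.83 for Foxa1. Between organoids and progenitor cells 535 passed, with 5.31 for Saa1, 4.06 for S1pr3, 3.78 for Ccl7, 3.67 for Dcn, 3.66 for Tmem52b, -3.98 for Tmprss11a, -3.95 for Cxcl15, -3.87 for Akr1c14, -3.76 for Dkk2 and -3.70 for Enpp3. Signals outside the gene tests were the poly-A controls, which lay 5.14 log2 units higher on the lowest other array than on the highest organoid array, and 1310 of 2911 bright probe sets without a gene name that passed between progenitor cells and tissue.

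The splits of the arrays cannot exclude chance as a source of the 3 stage counts. In a fit of the 8 arrays as 2 groups, the real split was 1 of 35 splits with as many genes, with 10132 genes for progenitor against tissue, 8463 for organoid against progenitor and 9377 for organoid against tissue, where the highest other split gave 0 each time. Every other split put arrays of both stages on each side, so the stage difference itself widened the spread and held those counts down. These splits also say nothing about a technical difference that runs with the stage.

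The organoid arrays stood apart from the other 8. Labelling in another batch, or without the added controls, could account for part of this: the poly-A gap of 5.14 log2 units was there on all 4 organoid arrays, while hybridization controls were not lower. RNA degradation stays open, since from progenitor to organoid arrays the 3' minus 5' difference of beta-actin changed by -0.102 while that of Gapdh changed by 1.65, so the control transcripts disagree. Whether labelling is the whole cause of the calls between organoids and progenitor cells cannot be told apart from the culture stage, because every organoid array carries the difference; other probe sets of called genes took their sign in 60.1% of cases. A biological difference between the stages stays open and was not tested apart from it.

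Fibroblast genes were higher in medulla organoids than in cortex organoids. A single aberrant array is argued against, since between 11 and 17 of 19 members were called with each organoid array left out. Feeder fibroblasts carried into the medulla organoids may be a source, and the smooth muscle and pericyte list, with genes such as Acta2 and Tagln, had a median difference of -0.261. That value cannot settle it because no feeder cells were measured on an array of their own. From progenitor to organoid arrays the list mean went from 9.08 on both to 6.44 and 6.89 in the cortex. In the medulla it went from 9.46 and 9.51 to 8.84 and 8.69, so the gap came with a larger fall in the cortex. A mesenchymal part of the medulla-derived cultures is 1 possible biological explanation, and it was not tested.

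Medulla tissue kept most of the signal of cortex genes. Cortex included in the medulla samples could account for this, since podocyte genes, whose glomeruli lie in the cortex, had a median difference of -0.413 (SD over genes 0.329). Medulla replicate 2 alone is argued against, because replicate 1 by itself had a podocyte median of -0.628. Compression of very bright signals may add to it: the 8 proximal tubule genes under 13 in cortex tissue had a median difference -0.473 below that of the 23 brighter ones (-0.741 and -0.268, permutation p = 0.00021 over 100000 resamples, genes not independent, limit chosen after seeing the data). Proximal tubules that reach into the outer medulla are a biological explanation for the tubule genes, and it was not tested.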

How the results depend on the processing

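The comparisons of 3 stages kept their direction and stayed within 1.5 times of their counts under every alternative except the check on other probe sets. That check, chosen after seeing the data, gave 2586 genes for progenitor against tissue, 1655 for organoid against progenitor, 2342 for organoid against tissue, 1, 4 and 186 for medulla against cortex in tissue, progenitors and organoids, 4 for progenitors minus tissue and 31 for organoids minus progenitors. Genes with 1 bright probe set drop out by construction, and of the 4752, 4782, 5100, 24, 17, 1233, 17 and 279 called genes with more, in the order of the next paragraph, the rest had a probe set not called the same way. Region counts moved more. In tissue they were 27 with the mean of all probe sets, 1 in a fit of only the groups compared and 21 without the variance trend. In progenitors they were 63 with the offset at the median and 145 with only the groups compared, and in organoids 240 with only the groups compared. The region difference in progenitors minus tissue gave 71 with only the groups compared and 23 without trend, and that in organoids minus progenitors gave 266 with only the groups compared. A fit of only the compared groups no longer shares the spread with the other groups. The cause of the other changes was not tested.

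With each array left out in turn, where the lone array of its group is assumed to vary like the other groups, the counts ranged from 8814 to 10225 for progenitor against tissue, 8751 to 9931 for organoid against progenitor, 9896 to 10759 for organoid against tissue, 14 to 229, 13 to 105 and 1060 to 4316 for medulla against cortex in tissue, progenitors and organoids, 11 to 122 for progenitors minus tissue and 124 to 2509 for organoids minus progenitors.

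No pairing by replicate number was detected: over 15 pairs of groups, deviations of equally numbered arrays correlated between -0.14 and 0.057, with 0 pairs over 0.1. With 2 arrays per group this cannot show that equal numbers came from different animals or cultures. With the replicate block the counts, in the order of the last paragraph, were 9415, 9386, 10350, 34, 39, 2134, 36 and 407. The median of the tissue region genes in progenitors, -0.042 in the main setting, became 0.0572 with the replicate block. For the tissue genes changed at least 2-fold it was -0.0103 and the direction of limma's rotation test turned, without passing in either case. For the genes above the array median in that culture, a setting chosen after seeing the data, the medians were -0.0774 in progenitors and -0.0951 in organoids.

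The largest rises and falls and the marker genes were followed through the settings, each counted once per comparison. Of these values past the threshold, 38 of 168 lost or changed the call in some setting. A gene that a setting filtered out was skipped there and does not count as lost. Genes named only as members of a list were not followed in this way. Slc14a2 in progenitors minus tissue turned to 0.20 at an offset of 1 (adjusted p = 0.999), because another probe set then became the brightest. Genes that had not passed turned sign: with the mean of all probe sets, Lrp2 in organoid against progenitor (-0.35), Col1a1 (-0.24) and Trp63 (-0.11) in tissue, Trp63 in progenitors (0.13), and Trp63 (-0.0789) and Ptprc (-0.0853) in organoids. With the offset at the median, Lrp2 turned in organoid against progenitor (-0.0716) and in organoids (0.0289), and with quantile normalization Vim turned in organoid against progenitor (0.0106). With each array left out, other such genes ranged through 0: in organoid against progenitor Lrp2 -0.063 to 0.601, Vim -0.200 to 0.0129, Trp63 -0.0129 to 0.685; in medulla against cortex in tissue Sox9 -1.22 to 0.351, Pecam1 -0.0991 to 0.338, Ptprc -0.0217 to 0.346; in medulla against cortex in progenitors Epcam -0.0355 to 0.204, Cdh1 -0.337 to 0.0125, Lrp2 -0.339 to 0.496, Slc34a1 -0.129 to 0.535, Aqp2 -0.064 to 0.443, Krt5 -0.0851 to 0.325, Ptprc -0.238 to 0.13; in medulla against cortex in organoids Lrp2 -0.821 to 0.507, Mki67 -0.282 to 0.319, Pecam1 -0.0424 to 0.599, Ptprc -0.243 to 0.359. Their cause was not tested. Every called list kept its direction, while 108 values under other settings and 43 with an array left out lost the call. Levels near background limit the rest, because a fold against a dim group depends on the offset.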

Other observations

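Every test in this part was chosen after the result was seen. Region differences of the progenitor cells recurred in the organoids more than independent lists would share. Of 36 genes higher in medulla-derived progenitor cells, 20 were also higher in medulla organoids, against 2.86 for independent lists (Fisher's exact test, p = 1.78e-13, genes not independent). They were Adgrf5, Aqp1, Cdo1, Cldn2, Crispld2, Ctla2a, Defb1, Efemp1, Enpep, Gata3, Kit, Ldhd, Plagl1, Pmp22, Slc27a2, Spink8, Sprr2f, St8sia6, Stard8 and Zfp503. Irs1 and Klf4 were lower in medulla in both. The progenitor and organoid arrays are separate samples, but both region differences use the same variance of each gene. Independent lists are therefore not a neutral reference, and the p-value of Fisher's test can overstate the evidence.

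The shared count was 11 and 12 without cortex progenitor replicates 1 and 2, 8 and 10 without medulla progenitor replicates 1 and 2, 16 and 18 without cortex organoid replicates 1 and 2, and 35 and 38 without medulla organoid replicates 1 and 2. Across all 13037 genes the region differences of progenitors and organoids correlated with r = 0.146, those of tissue and progenitors with 0.0235 and those of tissue and organoids with -0.0195. Whether the shared genes reflect the region or the particular cultures was not tested. Tissue shared only Plet1 with progenitor cells (0.119 for independent lists) and Dst and Upk3b with organoids (3.41 for independent lists).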
